A study of Homo sapiens with 6 samples.

How the data were processed

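Total RNA of neural progenitor cells derived from the human embryonic stem cell line H9 was made into libraries with a stranded total RNA kit, per the labels, in 3 groups of 2 libraries: control, knockdown-1 and knockdown-2, which are 2 shRNAs against PRMT7. The authors deposited 1 table of estimated counts per gene, with 61544 versioned Ensembl gene IDs and 6 libraries. The values are expected counts that were not scaled between libraries, as between 9.5% and 9.8% of the values of a library were not whole within 0.005. Per the submitters' processing notes, FastQC 0.11.2, cutadapt 3.3, STAR 2.7.9a and Salmon 1.4.0 were used with the builds GRCh38.p12 and hg38, without their roles. The counting program, the annotation release and the strand setting are not given in the sources used here, so genes that share exons with another gene, or reads with a near-identical copy, are uncertain. Of 114 named genes, 49 share an exon base with another gene in GENCODE 29 and 9 share at least 20% of their exon bases. Among these, 4 share them with a tested gene and are marked where they are named. CYP51A1 (79.4%, same strand), MCM2 (22.7%, antisense), RRM2 (20.2%, same strand) and SNRPB (20.0%, same strand) share them with genes that were not tested, and are uncertain too. Library totals ranged from 16278423 to 17428019, mitochondrial genes took from 2.99% to 3.55% of the counts, and the most abundant gene, EEF1A1, took from 0.832% to 1.12%.

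Symbols came from a table of gene names, which had an entry for 61445 IDs, and coordinates, biotypes, exon length and GC content from GENCODE 29 on GRCh38, which held 58342 of the IDs. Pseudoautosomal genes of the second sex chromosome had 46 separate IDs, which were kept as deposited. Counts were rounded to whole numbers, filtered with filterByExpr (minimum count 10), scaled by TMM and fitted in edgeR 4.0.16 under R 4.3.3 with the quasi-likelihood model over all 6 libraries, so that the 3 groups shared 1 estimate of the spread. The common biological coefficient of variation was 0.027, with 3 residual and 14.3 prior degrees of freedom. Contrasts were each shRNA against control, their mean against control, and knockdown-2 against knockdown-1. Tests were two-sided with Benjamini-Hochberg adjustment over 17530 genes and a threshold of 0.05. Standard errors were the log2 fold change over the square root of F, and levels are CPM, counts scaled to a common library size with the TMM factors. Of 55 gene lists, 53 had at least 5 tested members and were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. With an estimated correlation, camera rests on the 3 residual degrees of freedom, so a list passes less easily. A call lost at that setting does not show that a list was unchanged. Counts of list members were also adjusted over the list alone.

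The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took PRMT7 first, then the 12 genes that rose and the 12 that fell most by the smaller of the 2 changes, among genes called with both shRNAs the same way, with a mean of at least 2 CPM and every knockdown library beyond both control libraries. It then took the 5 genes highest and the 5 lowest with knockdown-2 against knockdown-1, among protein-coding and named long non-coding RNA genes that differed, with a mean of at least 2 CPM and no overlap between the libraries of the shRNAs, and up to 4 members of a list with the smallest p in the mean contrast. A pair of genes taken by this rule is not reported here. The overlap of calls was set against independent lists and against 20 simulations of unchanged groups. In these, all libraries, controls included, were drawn at the mean control levels, and both comparisons shared the simulated controls. The steps were tested on simulated counts for the 17530 genes. For knockdown-1 against control, 38% of 50 genes changed by 1.25-fold, 68% at 1.5-fold, 74% at 2-fold and 90% at 4-fold were recovered, and 11 of 17293 unchanged genes were called. DNA repair genes, lowered there by 0.3 on the log2 scale, were called as a list at both settings (camera adjusted p = 0.0454 with an estimated correlation). At the preset correlation 3 other lists were called, each holding a changed gene, and 0 with an estimated one. Alternatives were median-of-ratios and upper-quartile scaling, no filter and a filter of 1 CPM, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, a replicate block, a 2-fold threshold, and leaving out each library in turn.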

Results

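Neural progenitor cells (NPCs), the dividing precursors of neurons and glia, were derived from H9, an established human embryonic stem cell line, and their total RNA was sequenced. PRMT7, which encodes a protein arginine methyltransferase, was targeted with 2 different short hairpin RNAs (shRNAs), called knockdown-1 and knockdown-2 here. The study asked how a lower PRMT7 level bears on schizophrenia risk through NPC function. There were 3 groups, control, knockdown-1 and knockdown-2, of 2 libraries each. The deposited table held 17428019 and 17291331 estimated counts for the control libraries, 16819047 and 16278423 for knockdown-1, and 17017057 and 17018623 for knockdown-2. After a filter on low counts, 17530 genes were tested, of which 14351 were protein-coding. Replicates of a group correlated across genes at 0.997 (control), 0.996 (knockdown-1) and 0.997 (knockdown-2) on the log2 scale, and differed by more than sampling noise, with a chi-square per degree of freedom of 1.91, 2.04 and 1.83. The first principal component, with 57.5% of the variance, placed knockdown-1 at one end, knockdown-2 at the other and the controls between them. The second, with 21.4%, separated the controls from both knockdown groups. The labels do not say that the libraries of a group came from separate cultures, so every p-value of a gene measures only the spread between these samples, which may be technical. Camera at the preset correlation compares the genes of a list with the other tested genes. Its p-values do not measure the spread between separate cultures either.

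PRMT7 was lower than control with both shRNAs and lowest with knockdown-1. The gene (ENSG00000132600.18, protein-coding) lies on the plus strand of chromosome 16 from 68310974 to 68358563 in GRCh38. Its level in CPM, the count scaled to a common library size, was 84.7 ± 1.01 CPM (SD, n = 2) in control, 33.8 ± 3.57 CPM with knockdown-1 and 63.2 ± 0.38 CPM with knockdown-2, or 39.9% and 74.6% of control. The replicates read 84.0 and 85.4 CPM in control, 36.4 and 31.3 CPM with knockdown-1, and 63.4 and 62.9 CPM with knockdown-2, from 500 to 1475 counts per library. The log2 fold change was -1.32 ± 0.062 (SE) with knockdown-1 and -0.42 ± 0.055 with knockdown-2, with edgeR quasi-likelihood adjusted p-values of 9.90e-12 and 9.10e-06. The difference between the shRNAs, 0.90 ± 0.064, also passed the same edgeR test (adjusted p = 1.90e-09).

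**Figure D1:**
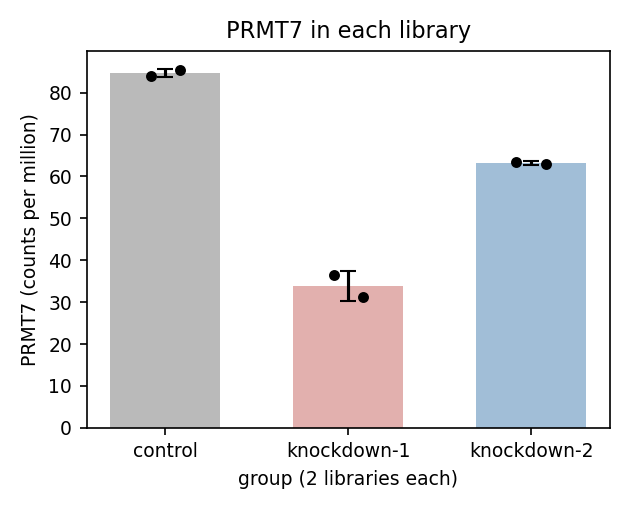
PRMT7 level in CPM in each library, with black points for the 2 libraries of a group, bars for the group mean and error bars for the SD. The control libraries lie at 84.0 and 85.4 CPM, knockdown-2 at 63.4 and 62.9 CPM, and knockdown-1 at 36.4 and 31.3 CPM.

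With knockdown-1, interferon-stimulated genes and genes of the unfolded protein response rose together. Of 33 tested interferon-stimulated and double-stranded RNA sensor genes, 33 were higher than control (33 adjusted over the list alone), with a median log2 fold change of 1.81. MX1, which encodes an antiviral GTPase, went from 59.0 ± 1.82 CPM (SD, n = 2) to 143 ± 0.310 CPM, and OAS2, which encodes an enzyme activated by double-stranded RNA, from 25.4 ± 0.620 to 96.8 ± 0.132 CPM. IFI44L and OAS1 rose by 1.36 ± 0.044 and 1.38 ± 0.064 on the log2 scale (SE). The camera test called this list higher (adjusted p = 6.69e-130), also with an estimated correlation (adjusted p = 0.0051 with an estimated correlation). Of 21 unfolded protein response genes, 20 rose (20 adjusted over the list alone), with a median of 0.82, and this call held as well (adjusted p = 0.0107 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, went from 984 ± 23.4 to 2068 ± 5.35 CPM, PDIA4 from 434 ± 1.82 to 1019 ± 4.12 CPM, and DNAJC3 rose by 1.58 ± 0.050 on the log2 scale.

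Other stress and signalling lists rose with knockdown-1 under camera's preset correlation and lost the call with an estimated one. The estimated setting rests on only 3 residual degrees of freedom, so a lost call, here and below, does not show an unchanged list. Of 27 targets of the stress-response factor ATF4, 21 rose and 1 fell (22 and 2 adjusted over the list alone; adjusted p = 0.0719 with an estimated correlation). WARS1, a tryptophanyl-tRNA synthetase gene, rose by 0.99 ± 0.039. Immediate early genes rose in 16 of 23 cases and fell in 1 (17 and 1 adjusted over the list alone; adjusted p = 0.0719 with an estimated correlation). KLF4 went from 2.34 ± 0.134 to 24.4 ± 0.581 CPM, and the matrix-associated genes CCN2 and CCN1 rose by 1.58 ± 0.031 and 1.16 ± 0.034. Targets of the oxidative stress factor NRF2 rose in 14 of 18 cases and fell in 1 (15 and 2 adjusted over the list alone; adjusted p = 0.0846 with an estimated correlation). NQO1 rose by 1.18 ± 0.035 and TXNRD1 by 0.57 ± 0.037. Cholesterol synthesis genes rose in 18 of 25 cases and fell in 3 (19 and 3 adjusted over the list alone; adjusted p = 0.0740 with an estimated correlation). CYP51A1 rose by 0.62 ± 0.035, and is uncertain because 79.4% of its exon bases overlap another gene on the same strand. Mesenchymal and fibroblast markers, a cell type other than NPCs, were higher in 11 of 17 cases and lower in 2 (12 and 2 adjusted over the list alone; adjusted p = 0.0652 with an estimated correlation). The smooth muscle actin gene ACTA2 went from 144 ± 3.14 to 311 ± 17 CPM, and TAGLN rose by 0.89 ± 0.033.

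Progenitor and patterning genes fell with knockdown-1. Of 22 neural progenitor and radial glia markers, 15 fell and 3 rose (15 and 3 adjusted over the list alone; adjusted p = 0.0968 with an estimated correlation). SOX2, a transcription factor of neural stem cells, went from 109 ± 4.72 to 67.5 ± 2.27 CPM, HMGA2 and MSI2 changed by -0.47 and -0.59 on the log2 scale, and the matrix protein gene TNC rose by 1.14 ± 0.059. Forebrain regional factors fell in 12 of 16 cases and rose in 0 (13 and 0 adjusted over the list alone; adjusted p = 0.2618 with an estimated correlation). OTX2 was at -0.77 ± 0.039 and EMX2 at -0.82 ± 0.061. Wnt pathway genes fell in 22 of 36 cases and rose in 5 (24 and 5 adjusted over the list alone; adjusted p = 0.0532 with an estimated correlation). The ligand gene WNT8B went from 154 ± 3.89 to 49.0 ± 0.643 CPM, and WNT4 from 80.5 ± 5.07 to 25.8 ± 0.565 CPM. Cytosolic ribosomal protein genes fell in 50 of 52 cases (50 adjusted over the list alone; adjusted p = 0.2216 with an estimated correlation). RPL26 was at -1.03 ± 0.036 and RPL5 at -0.47 ± 0.032, both uncertain because they have processed pseudogenes and fractional counts. In all, 7566 genes changed with knockdown-1 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), 3861 higher and 3705 lower, of which 1080 changed by 2-fold or more. DESeq2 called 4794. Of 53 lists tested, camera called 13 higher and 14 lower, and the 2 named above kept the call with an estimated correlation.

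With knockdown-2, most interferon-stimulated genes were lower than control, and most ribosome biogenesis genes fell, while part of the neuronal, presynaptic and cilium genes rose. The interferon list kept its call with an estimated correlation, and the ribosome biogenesis, neuronal, presynaptic and cilium lists lost theirs (adjusted p = 0.0667, 0.0872, 0.0667 and 0.0861 with an estimated correlation). Of 33 interferon-stimulated and double-stranded RNA sensor genes, 28 fell and 0 rose (28 and 0 adjusted over the list alone), with a median log2 fold change of -2.09, or -1.65 with CXCL10, with no count in knockdown-2, set at its bound of 3 counts over the group (adjusted p = 0.0087 with an estimated correlation). MX1 was at 3.06 ± 0.0110 CPM (SD, n = 2) against 59.0 ± 1.82 CPM in control, IFI44L at 5.37 ± 0.182 against 66.6 ± 0.882 CPM, OAS1 at 1.16 ± 0.331 against 28.9 ± 2.31 CPM, and OAS2 at 0.838 ± 0.289 against 25.4 ± 0.620 CPM. Unfolded protein response genes were not called (camera adjusted p = 0.9712, upward against a median of -0.02), with 4 higher and 6 lower of 21 (4 and 7 adjusted over the list alone), and HSPA5 stood at 982 ± 10.1 CPM. The lower count was 3 without control replicate 1 and 2 without knockdown-2 replicate 2. ATF4 targets fell in 19 of 27 cases and rose in 4 (19 and 4 adjusted over the list alone; adjusted p = 0.1112 with an estimated correlation). PHGDH, the entry enzyme of serine synthesis, was at -0.45 ± 0.044, while ATF3 and SESN2 rose by 0.40 ± 0.044 and 0.43 ± 0.054. Neuronal markers rose in 13 of 20 cases and fell in 2 (13 and 2 adjusted over the list alone; adjusted p = 0.0872 with an estimated correlation). DCX, a microtubule protein gene of young neurons, went from 30.1 ± 2.33 to 75.1 ± 1.21 CPM, NEFM rose by 0.83 ± 0.052 and NEFL by 0.50 ± 0.049, and THY1 changed by -1.08 ± 0.060 on the log2 scale. Among markers of other cell types, camera also called astrocyte markers higher, with 5 of 13 higher and 2 lower (6 and 2 adjusted over the list alone; adjusted p = 0.1768 with an estimated correlation). It called endothelial and microglial markers lower, with 5 of 9 lower and 1 higher (5 and 1 adjusted over the list alone; adjusted p = 0.1435 with an estimated correlation). Presynaptic and vesicle release genes rose in 10 of 25 cases and fell in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.0667 with an estimated correlation). The complexin gene CPLX2 went from 11.7 ± 0.225 to 84.6 ± 2.46 CPM, and the active zone genes BSN and PCLO rose by 0.98 ± 0.081 and 0.88 ± 0.088. Cilium and centrosome genes rose in 16 of 33 cases and fell in 2 (19 and 2 adjusted over the list alone; adjusted p = 0.0861 with an estimated correlation), and 10 of them were higher without knockdown-2 replicate 1. FOXJ1, a master factor of motile cilia, went from 18.1 ± 0.0520 to 80 ± 4.0 CPM. Axon guidance genes rose in 18 of 42 cases and fell in 5 (21 and 5 adjusted over the list alone; adjusted p = 0.0985 with an estimated correlation). PLXNC1 rose by 1.249 ± 0.062, UNC5D rose by 0.60 ± 0.041 and NRP2 was at -0.67 ± 0.033. Forebrain regional factors rose in 7 of 16 cases and fell in 4 (8 and 4 adjusted over the list alone; adjusted p = 0.4292 with an estimated correlation). ZIC1 rose by 0.78 ± 0.036, and OTX2 and EMX2 were lower at -0.26 ± 0.037 and -0.54 ± 0.058. In all, 6088 genes changed with knockdown-2 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), 2870 higher and 3218 lower, of which 634 changed by 2-fold or more. DESeq2 called 3481. Camera called 10 lists higher and 11 lower, and the interferon and G1/S lists kept the call with an estimated correlation. The rise of neuronal and presynaptic genes was not particular to knockdown-2. With knockdown-1, 10 neuronal markers rose and 6 fell, and 11 presynaptic genes rose and 3 fell, though camera called neither list. Nor did camera call either list different between the shRNAs, with median differences of 0.10 and 0.15.

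**Figure D2:**
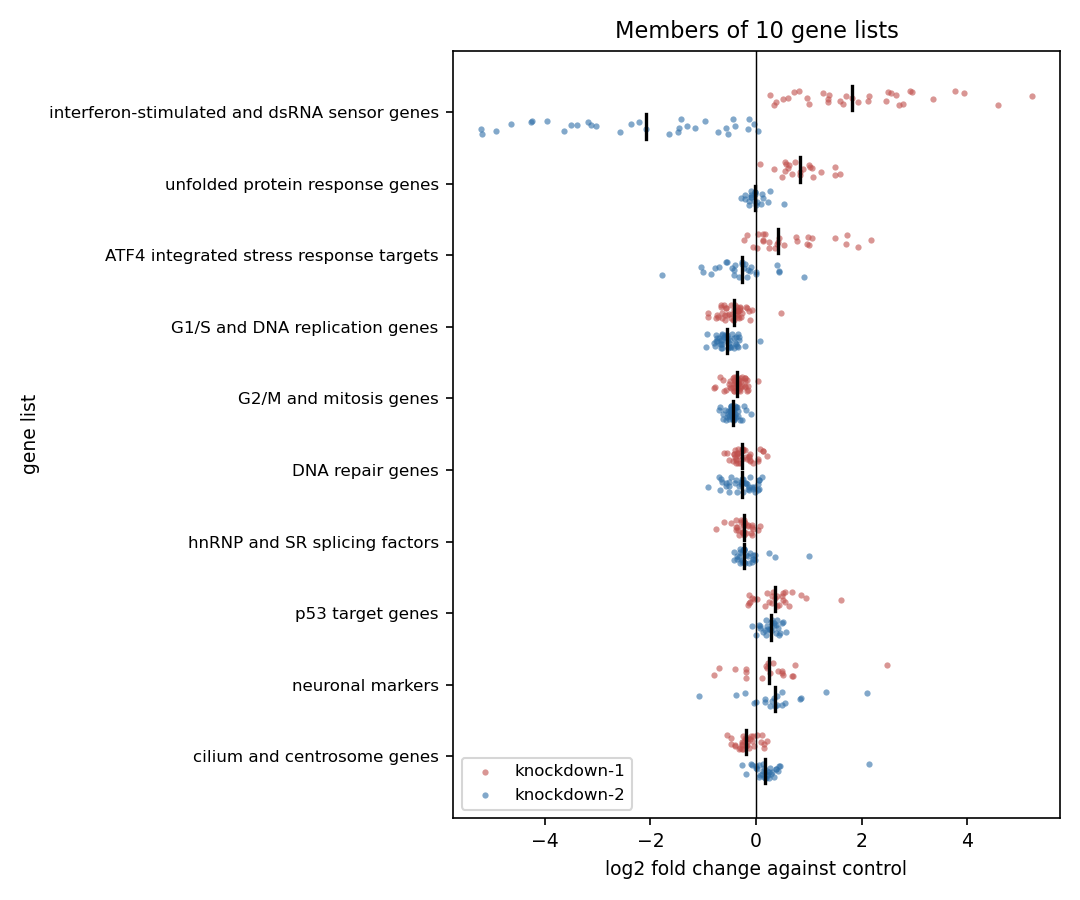
Log2 fold change against control of each tested member of 10 gene lists, with red points for knockdown-1, blue points for knockdown-2 and black bars for the list median. The interferon-stimulated genes have medians of 1.81 and -2.09, while the G1/S genes have medians of -0.41 and -0.54.

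The genes changed the same way by both shRNAs are the comparison that the use of 2 hairpins against 1 target addresses. Cell cycle genes fell with both. Of 43 G1/S and DNA replication genes, 39 fell and 1 rose with knockdown-1, and 42 fell with knockdown-2 (the same counts adjusted over the list alone), with medians of -0.41 and -0.54 (adjusted p = 0.0532 and 0.0374 with an estimated correlation). MCM2, a subunit of the replicative helicase, went from 150.3 ± 1.75 CPM in control to 91.5 ± 1.08 and 87.3 ± 2.63 CPM (SD, n = 2), MCM4 changed by -0.66 and -0.64 on the log2 scale, and RRM2, a subunit of ribonucleotide reductase, by -0.55 and -0.68. Of 47 G2/M and mitosis genes, 45 fell with knockdown-1 and 46 with knockdown-2 (the same counts adjusted over the list alone; adjusted p = 0.0846 and 0.0667 with an estimated correlation). MKI67, a proliferation marker, went from 497 ± 10.9 to 327 ± 24.5 and 337 ± 6.17 CPM, and CENPF and ECT2 changed by -0.57 and -0.80 with knockdown-1 and by -0.41 and -0.46 with knockdown-2. Cell cycle inhibitors and cyclin D genes rose in 9 and 11 of 19 cases and fell in 3 and 4 (10 and 11 higher adjusted over the list alone; adjusted p = 0.1087 and 0.0985 with an estimated correlation). With knockdown-2, 2 of them fell without control replicate 1 and 1 without knockdown-2 replicate 2. CDKN2B was at 0.62 ± 0.036 and 0.95 ± 0.035, GADD45A at 0.89 ± 0.053 and 0.22 ± 0.056, and BTG2 at 0.50 ± 0.056 and 0.51 ± 0.056. Targets of the tumour suppressor p53 rose in 20 and 21 of 27 cases and fell in 2 and 0 (20 and 22 against 2 and 0 adjusted over the list alone; adjusted p = 0.0719 and 0.0688 with an estimated correlation). The kinase inhibitor gene CDKN1A was at 0.85 ± 0.033 and 0.48 ± 0.033 and MDM2 at 0.54 ± 0.036 and 0.19 ± 0.036.

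Most DNA repair genes and most hnRNP and SR splicing factors also fell with both shRNAs, and other RNA-processing genes did so less evenly. Splicing factors of the hnRNP and SR families fell in 23 and 22 of 31 cases and rose in 0 and 3 (24 and 22 against 0 and 3 adjusted over the list alone; adjusted p = 0.0740 and 0.0985 with an estimated correlation). SRSF7 was at -0.75 ± 0.041 and -0.32 ± 0.039, HNRNPC at -0.38 ± 0.030 and -0.37 ± 0.030, and HNRNPD at -0.48 ± 0.038 and -0.42 ± 0.038. DNA repair genes fell in 25 and 23 of 38 cases and rose in 1 and 0 (27 and 26 against 2 and 0 adjusted over the list alone; adjusted p = 0.0719 and 0.0667 with an estimated correlation). BRCA1 was at -0.60 ± 0.060 and -0.64 ± 0.059 and FANCI at -0.39 ± 0.043 and -0.52 ± 0.043. Ribosome biogenesis genes fell in 11 and 28 of 31 cases (11 and 30 adjusted over the list alone; adjusted p = 0.2194 and 0.0667 with an estimated correlation). The nucleolar genes NPM1, FBL and DDX21 were at -0.38 ± 0.031, -0.58 ± 0.050 and -0.53 ± 0.038 with knockdown-2. Sm ring and spliceosome assembly genes fell in 9 and 13 of 21 cases and rose in 2 and 1 (9 and 13 against 2 and 1 adjusted over the list alone), were called with knockdown-2 and not with knockdown-1 by camera (adjusted p = 0.0027 and 0.1296), and lost the knockdown-2 call with an estimated correlation (adjusted p = 0.1978 with an estimated correlation). Among them SNRPD1 was at -0.34 ± 0.052 and -0.43 ± 0.052 and SNRPB at -0.23 ± 0.040 and -0.43 ± 0.041. Pluripotency markers fell in 4 and 3 of 7 tested cases and rose in 1 and 0 (4 and 3 against 1 and 0 adjusted over the list alone; adjusted p = 0.0783 and 0.0990 with an estimated correlation). LIN28A, which encodes an RNA-binding protein of stem and early progenitor cells, went from 549.8 ± 1.72 CPM in control to 247 ± 9.30 and 249 ± 8.75 CPM, and DNMT3B and DPPA4 changed by -1.09 and -0.66 with knockdown-1 and by -0.45 and -0.29 with knockdown-2. SFRP2 and SFRP1, secreted Wnt antagonists, changed by -0.95 and -0.95 with knockdown-1 and by -1.08 and -0.77 with knockdown-2.

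Ranked by the smaller of the 2 changes, the genes that rose most with both shRNAs were ADCYAP1, TRIM67, UNC13A, RYR2, PCSK1N, NOL4, AP3B2, PADI2, DISP2, CLDN11, MMP24 and FRMPD1. ADCYAP1, which encodes a neuropeptide, went from 0.578 ± 0.329 CPM in control to 3.85 ± 0.129 and 2.68 ± 0.685 CPM (SD, n = 2), and UNC13A, a synaptic vesicle priming gene, from 10.5 ± 0.340 to 35.1 ± 1.86 and 31.2 ± 0.477 CPM. RYR2, an intracellular calcium channel gene, changed by 1.32 ± 0.19 and 1.30 ± 0.19 on the log2 scale, and AP3B2, a neuronal vesicle adaptor gene, by 1.27 ± 0.14 and 1.62 ± 0.13. MMP24 rose by 1.20 ± 0.087 and 1.73 ± 0.081, and is uncertain because its counts were fractional in every library. The genes that fell most with both were ALDH1A1, CYSLTR2, IL2RB, NDNF, LGR5, ANO3, COL6A3, PLEKHD1, MIR302CHG, HHIP, NOS2 and LIN28A. ALDH1A1, a retinaldehyde dehydrogenase gene, went from 5.71 ± 0.111 to 1.04 ± 0.238 and 1.42 ± 0.454 CPM, the collagen gene COL6A3 from 63.6 ± 3.06 to 25.9 ± 1.44 and 23.5 ± 3.10 CPM, and HHIP, an inhibitor of hedgehog ligands, from 38.1 ± 0.604 to 16.2 ± 0.209 and 15.8 ± 0.108 CPM. The Wnt receptor gene LGR5 changed by -1.56 ± 0.27 and -1.34 ± 0.26, and NDNF by -1.76 ± 0.18 and -1.34 ± 0.16. MIR302CHG, the host gene of the stem cell microRNA cluster miR-302, changed by -1.25 and -1.33, and is uncertain because 40.6% of its exon bases overlap LARP7 on the other strand and its counts were fractional. These 24 genes passed the edgeR quasi-likelihood test in both comparisons at adjusted p-values of 0.0043 or less.

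In all, 2377 genes changed the same way with both shRNAs, 997 higher and 1380 lower, and 116 did so by 2-fold or more. Independent lists of these sizes would share 632 higher and 680 lower genes. Genes called in opposite directions numbered 656 (higher with knockdown-1) and 600 (lower with knockdown-1), against 709 and 607 from independent lists. Both comparisons used the same control libraries. Simulated unchanged groups that shared simulated controls had 0.3 calls the same way on average over 20 simulations. With no gene changed, few calls were possible there. This value therefore cannot show how much the shared controls add to the overlap. The controls were not split between the comparisons, since each comparison would keep 1 control library, so part of the excess may come from the shared controls. Across the 17530 genes, which are not independent replicates, the log2 fold changes of the 2 shRNAs had a Pearson correlation of 0.103 and a Spearman correlation of 0.182, against 0.499 and 0.437 in the simulated groups. The covariance was 0.036 against 0.034 simulated, a difference of 0.002. As no gene was changed in the simulated groups, the simulated values hold only noise and shared controls. They do not give the correlation to expect between shRNAs that change many genes. Without control replicate 1 the Pearson correlation was 0.30 and without control replicate 2 it was 0.233, and over 12245 genes of at least 5 CPM it was -0.011. Over the same 12245 genes the Spearman correlation was 0.197, and 58.4% of the genes had the same sign with both shRNAs, against 57.9% of all tested genes. Of the genes called the same way with both, 2194 were among these. DESeq2 called 1267 genes the same way with both.

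**Figure D3:**
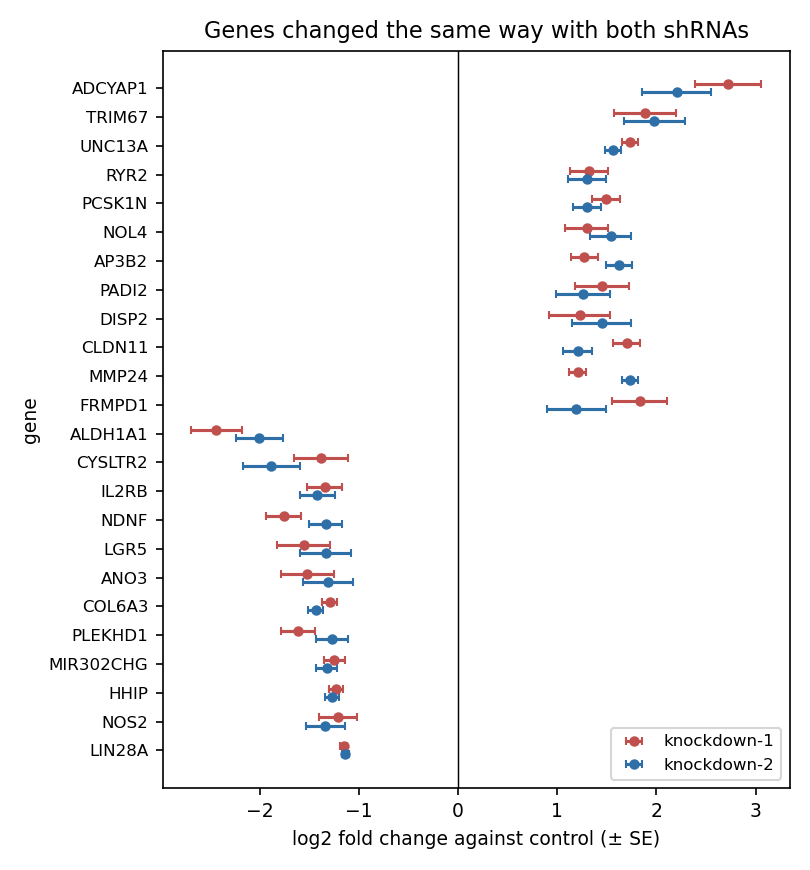
Log2 fold change against control (x axis, with SE) of the 12 genes that rose and the 12 that fell most with both shRNAs, in red for knockdown-1 and blue for knockdown-2. Both shRNAs lie on the same side of 0 for each gene, from 2.72 and 2.20 for ADCYAP1 to -2.44 and -2.01 for ALDH1A1.

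Averaged over both shRNAs, cell cycle genes fell and unfolded protein response genes rose. Of 43 G1/S genes 42 fell and 1 rose (42 and 1 adjusted over the list alone; adjusted p = 0.0265 with an estimated correlation), and of 47 G2/M genes 47 fell (47 adjusted over the list alone; adjusted p = 0.0628 with an estimated correlation). Unfolded protein response genes rose in 20 of 21 cases (20 adjusted over the list alone; adjusted p = 0.0265 with an estimated correlation), with CREB3L2 at 0.68 ± 0.035, where knockdown-1 had the call on its own and knockdown-2 had not. Targets of p53 rose in 21 of 27 cases (22 adjusted over the list alone; adjusted p = 0.0527 with an estimated correlation). Neuronal markers rose in 12 of 20 cases and fell in 2 (14 and 2 adjusted over the list alone; adjusted p = 0.0919 with an estimated correlation). Mesenchymal and fibroblast markers were higher in 10 of 17 cases and lower in 3 (10 and 3 adjusted over the list alone), and endothelial and microglial markers lower in 5 of 9 and higher in 0 (5 and 0 adjusted over the list alone), and both lists lost the call (adjusted p = 0.0919 and 0.1085 with an estimated correlation). Interferon-stimulated genes, which moved oppositely, had a mean-contrast median of -0.10, with 11 higher and 15 lower (12 and 15 adjusted over the list alone), but 7 higher without control replicate 1 and a median of 0.09 without control replicate 2. The mean contrast called 6067 genes in edgeR, 2969 higher and 3098 lower, 405 of them by 2-fold or more, and 21 lists, of which 2 kept the call with an estimated correlation. DESeq2 called 3521 genes, and a fit that pooled the 4 knockdown libraries as 1 group called 295.

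The direct comparison of knockdown-2 with knockdown-1 asked where the shRNAs differ. Interferon-stimulated genes were lower and several regulators of motile cilia higher with knockdown-2. All 33 interferon-stimulated genes were lower with knockdown-2 than with knockdown-1 (33 adjusted over the list alone), with a median of -4.81 (adjusted p = 0.0022 with an estimated correlation). OASL stood at 47.7 ± 0.355 CPM (SD, n = 2) with knockdown-1 and 0.116 ± 0.0820 CPM with knockdown-2, and XAF1 at 25.0 ± 0.377 and 0.115 ± 0.163 CPM. The chemokine gene CCL5, which is not in that list, stood at 46.4 ± 1.89 and 0.202 ± 0.122 CPM against 0.317 ± 0.0420 CPM in control, and its change with knockdown-2 did not pass the test (edgeR adjusted p = 0.4942). The exons of XAF1 overlap those of an antisense gene over 38.3% of their bases, so XAF1 is uncertain, as are NEFM (38.9%, antisense) and BBS1 (53.9%, same strand). CXCL10 and CCL4L2 had no count in knockdown-2 against 6.35 ± 0.296 and 8.87 ± 0.676 CPM in knockdown-1, which is at least 73.3-fold and 102-fold lower against a floor of 3 counts over the group, and CCL4L2, which is not in that list either, is uncertain because it is nearly identical to CCL4. Among protein-coding and named long non-coding RNA genes with a mean of at least 2 CPM and no overlap between the libraries of the shRNAs, those with the largest excess in knockdown-2 were CDC20B, GMNC, GRIK1, HS3ST2 and TP73. GMNC, a regulator that starts multiciliated cell differentiation, was at 22.2 ± 0.865 CPM in control, 7.34 ± 0.423 CPM with knockdown-1 and 80.7 ± 5.76 CPM with knockdown-2, and CDC20B, which hosts a microRNA cluster of multiciliated cells, at 4.07 ± 0.591, 1.18 ± 0.462 and 19.6 ± 0.176 CPM. TP73, a p53 family gene, was at 0.677 ± 0.0720 and 6.96 ± 0.800 CPM with the shRNAs, GRIK1, a kainate receptor gene, at 0.767 ± 0.288 and 8.40 ± 0.910 CPM, and HS3ST2 at 0.648 ± 0.0580 and 6.79 ± 0.555 CPM. These 10 genes differed at edgeR adjusted p-values of 2.98e-09 or less.

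All 21 unfolded protein response genes were also lower with knockdown-2 than with knockdown-1 (21 adjusted over the list alone; adjusted p = 0.0173 with an estimated correlation). Cilium and centrosome genes were higher in 21 of 33 cases and lower in 1 (21 and 1 adjusted over the list alone; adjusted p = 0.0723 with an estimated correlation). FOXJ1 differed by 2.69 ± 0.071, IFT122 by 0.64 ± 0.056 and BBS1 by 0.45 ± 0.052. Wnt pathway genes were higher in 23 of 36 cases and lower in 6 (24 and 7 adjusted over the list alone; adjusted p = 0.0634 with an estimated correlation). WNT8B differed by 2.30 ± 0.044 and WNT4 by 1.69 ± 0.062. Mesenchymal and fibroblast markers were lower in 11 of 17 cases and higher in 2 (11 and 2 adjusted over the list alone; adjusted p = 0.0709 with an estimated correlation). The fibronectin gene FN1 differed by -0.90 ± 0.030. Extracellular matrix and integrin genes were lower in 22 of 42 cases and higher in 12 (23 and 12 adjusted over the list alone; adjusted p = 0.1550 with an estimated correlation), and against control with knockdown-2 their median was 0.00 while their mean was -0.10 and camera called them lower (adjusted p = 0.3345 with an estimated correlation). Ribosomal protein genes were higher in 45 of 52 cases (46 adjusted over the list alone; adjusted p = 0.4706 with an estimated correlation). G1/S genes, which fell with both shRNAs, did not differ as a list (camera adjusted p = 0.3299), with a median difference of -0.07. In all, 8337 genes differed between the shRNAs in the edgeR test, 4000 higher and 4337 lower with knockdown-2, 1606 of them by 2-fold or more, as did 20 lists by camera, of which the interferon and unfolded protein response lists kept the call with an estimated correlation.

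**Figure D4:**
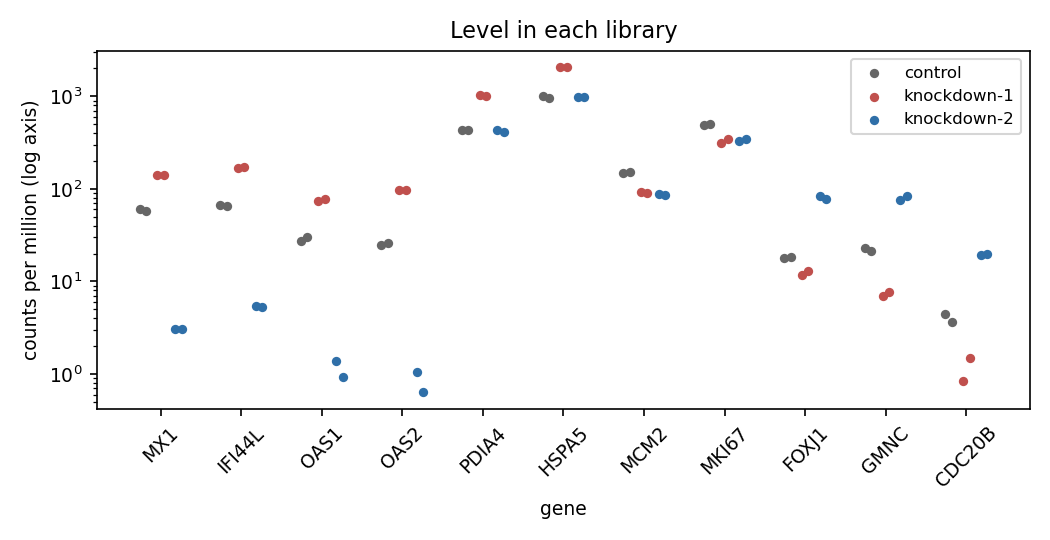
Level in CPM on a log axis of 11 genes in each of the 6 libraries, in grey for control, red for knockdown-1 and blue for knockdown-2. MX1 has group means of 59.0, 143 and 3.06 CPM, HSPA5 of 984, 2068 and 982 CPM, MCM2 of 150.3, 91.5 and 87.3 CPM, and GMNC of 22.2, 7.34 and 80.7 CPM.

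Genes linked to schizophrenia by exome and genome-wide association studies were not called as a list with either shRNA. Of 58 tested members, 16 rose and 17 fell with knockdown-1 (16 and 20 adjusted over the list alone), and 13 rose and 9 fell with knockdown-2 (13 and 9 adjusted over the list alone), and camera called neither (adjusted p = 0.6235 and 0.9520). Camera looks for a shared direction, so it does not show that the members were unchanged. Over all tested genes, 43.2% changed with knockdown-1 and 34.7% with knockdown-2. Whether the members changed more often than other genes was not tested. Without knockdown-1 replicate 1, 9 of the schizophrenia-associated genes from exome and genome-wide studies fell with knockdown-1. FURIN, a protein convertase gene, rose by 0.47 ± 0.044 and 0.29 ± 0.045, ZSWIM6 by 0.45 ± 0.056 and 0.39 ± 0.056, and NRGN, a postsynaptic calmodulin-binding protein gene, was at -0.55 ± 0.12 and -1.15 ± 0.13. Protein arginine methyltransferase and methylosome genes were not called as a list (camera adjusted p = 0.1882 and 0.1139), with 2 higher and 5 lower of 13 with knockdown-1 (2 and 6 adjusted over the list alone) and 1 higher and 6 lower with knockdown-2 (1 and 7 adjusted over the list alone). PRMT3 was at -0.75 ± 0.073 and -0.39 ± 0.069, PRMT1 at -0.28 ± 0.041 and -0.16 ± 0.040, and PRMT2 at 0.19 ± 0.042 and 0.22 ± 0.041. Among signs of RNA quality, mitochondrially encoded protein genes were not called with either shRNA (camera adjusted p = 0.4245 and 0.9712). Nuclear-retained and small structured RNAs fell in 6 of 12 cases with knockdown-1 and rose in 2 (6 and 2 adjusted over the list alone; adjusted p = 0.1562 with an estimated correlation), beside the lists above that changed with knockdown-1. With knockdown-2, 6 of them were higher and 5 lower (6 and 5 adjusted over the list alone), and camera did not call the list (adjusted p = 0.3356). RN7SL2 and RN7SL1, near-identical copies of the signal recognition particle RNA whose reads may be shared, went from 68.4 ± 19.3 to 5.4 ± 3.08 CPM and from 38.0 ± 12.2 to 4.52 ± 1.84 CPM with knockdown-1, and stood at 24.7 ± 3.34 and 18.1 ± 2.59 CPM with knockdown-2, where MALAT1 rose by 0.52 ± 0.033.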

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

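The test of the residual PRMT7 level was chosen after the result was seen, and the tests of the scaling and of leukocyte genes were written before their values were seen.

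The shRNAs differed from each other in 8337 genes by the edgeR test of the difference itself, and PRMT7 was higher with knockdown-2 by 0.90 on the log2 scale. Of 114 named genes, 82 differed between the shRNAs and 20 were called with both in opposite directions. Each value that follows is the log2 difference of knockdown-2 minus knockdown-1 and passed that test, or for a list is the median over its members. Camera called 20 lists different. Among those lower with knockdown-2, the medians were -4.81 for interferon-stimulated, -0.84 for unfolded protein response, -0.60 for ATF4 target, -1.10 for immediate early and -0.44 for NRF2 target genes. They were -0.35 for heat shock, -0.36 for cholesterol synthesis, -0.39 for mesenchymal, -0.24 for extracellular matrix, -0.23 for ribosome biogenesis and -0.16 for glycolysis and hypoxia genes. Among those higher with knockdown-2, they were 1.31 for nuclear-retained and small structured RNAs, 0.65 for forebrain factors, 0.44 for Wnt genes, 0.38 for cilium genes and 0.38 for astrocyte markers. They were 0.24 for ribosomal proteins, 0.20 for progenitor markers, 0.20 for postsynaptic genes and 0.16 for axon guidance genes. All but the interferon-stimulated and unfolded protein response lists lost the call with an estimated correlation, at adjusted p = 0.0634 to 0.4706 with an estimated correlation.

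Among genes of the interferon-stimulated group the difference was -8.60 for OASL, -7.67 for XAF1, -6.84 for OAS2, -6.02 for OAS1, -5.54 for MX1 and -4.99 for IFI44L. Against the floor of 3 counts over the knockdown-2 libraries, the bound was -6.20 for CXCL10 of this group. The chemokine genes CCL5 and CCL4L2, which are not in the list, differed by -7.79 and by a bound of -6.68. The chaperone and stress genes differed by -1.26 for PDIA4, -1.07 for HSPA5, -1.36 for DNAJC3, -0.29 for CREB3L2, -0.35 for ATF3, -1.003 for WARS1, -0.23 for PHGDH, -1.02 for NQO1 and -0.79 for TXNRD1. For immediate early genes and a sterol gene the values were -3.00 for KLF4, -1.96 for CCN2, -1.60 for CCN1 and -0.61 for CYP51A1. Cell cycle and p53-related genes differed by -0.14 for RRM2, 0.16 for CENPF, 0.33 for ECT2, -0.37 for CDKN1A, 0.34 for CDKN2B, -0.35 for MDM2 and -0.67 for GADD45A. For motile cilium regulators and other genes higher with knockdown-2 the values were 4.06 for CDC20B, 3.46 for GMNC, 3.35 for TP73, 2.69 for FOXJ1, 3.43 for GRIK1, 3.38 for HS3ST2, 0.64 for IFT122 and 0.45 for BBS1. Stem cell, repair and RNA-processing genes differed by 0.64 for DNMT3B, 0.37 for DPPA4, -0.12 for FANCI, 0.43 for SRSF7, 0.10 for NPM1, -0.40 for DDX21, -0.20 for SNRPB, 0.85 for RPL26 and 0.36 for RPL5. Progenitor and forebrain genes differed by 0.53 for SOX2, 0.20 for HMGA2, 0.41 for MSI2, -0.998 for TNC, 0.52 for OTX2, 0.28 for EMX2 and 1.00 for ZIC1. The neuronal, synaptic and guidance genes had values of 1.09 for DCX, -0.18 for NEFL, 0.42 for NEFM, -0.39 for THY1, 2.65 for CPLX2, 0.41 for BSN, -0.17 for UNC13A, 1.26 for PLXNC1, 0.50 for UNC5D, -0.56 for NRP2 and -0.60 for NRGN. Wnt-related genes differed by 2.30 for WNT8B, 1.69 for WNT4, 0.18 for SFRP1 and -0.12 for SFRP2. Mesenchymal genes differed by -1.03 for ACTA2, -0.51 for TAGLN and -0.90 for FN1. Among RNAs of the small structured and nuclear-retained group the values were 2.20 for RN7SL2, 2.01 for RN7SL1 and 0.40 for MALAT1. The remaining genes differed by 0.35 for AP3B2, -0.49 for CLDN11, 0.53 for MMP24, -0.64 for FRMPD1, -0.18 for FURIN, 0.35 for PRMT3 and 0.11 for PRMT1.

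Interferon-stimulated genes were higher than control with knockdown-1 and lower with knockdown-2. A response that follows the PRMT7 level alone would put both shRNAs on the same side of control, and 3.0% of the 33 members did so, which argues against it. The median difference moved by 0.058 log2 units over 4 scalings, which argues against scaling as the source. Of 15 leukocyte genes, 2, CD74 and CORO1A, reached 5 CPM in any group. CD74 stood at 8.60, 6.99 and 11.6 CPM in control, knockdown-1 and knockdown-2, opposite to the interferon pattern. CORO1A, at 4.42, 5.66 and 3.26 CPM, went the same way as that pattern. The low level of the other leukocyte genes argues against leukocytes as the source. A candidate explanation is a response to each hairpin apart from PRMT7, which was not tested, since whether the control cells received a hairpin is not given in the sources used here, and a response to PRMT7 that is not graded with its level stays open too. A difference between the cultures of the groups cannot be separated from the shRNA either.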

How the results depend on the processing

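All alternatives were chosen before the data were examined. The 2-fold threshold was applied to the counts of genes, and PRMT7 kept its direction and call under the other alternatives run on it, from -1.42 to -1.21 with knockdown-1, from -0.44 to -0.41 with knockdown-2 and from 0.79 to 1.00 between the shRNAs when libraries were left out. With 1 library left out, whose lone partner is assumed to vary like the other groups, 6052 to 7446 genes changed with knockdown-1, 4470 to 6063 with knockdown-2, 1766 to 2055 the same way with both, 4358 to 5552 with the mean and 6871 to 8341 between the shRNAs. Called lists then numbered 27 to 29, 20 to 22, 21 to 27 for the mean and 20 to 21 between the shRNAs, and the correlation of the fold changes ran from 0.077 to 0.30. That correlation was 0.419 with no filter on low counts, and the cause was not tested. DESeq2 called 4794, 3481, 1267 and 3521 genes for knockdown-1, knockdown-2, both the same way and the mean, and the cause was not tested. A threshold of 2-fold left 1080, 634, 116, 405 and 1606 genes, the last between the shRNAs, because it demands more. Pooling the 4 knockdown libraries as 1 group called 295 genes for the mean, since the difference between the shRNAs then counts as spread. In that fit 5 interferon-stimulated genes reversed, to 1.47 for XAF1, 0.30 for MX1, 0.40 for IFI44L, 0.40 for OAS1 and 0.94 for OAS2, with edgeR adjusted p from 0.74 to 0.94, because a pooled level is an arithmetic mean and the contrast a mean of logs. With an estimated correlation 2 lists were called for knockdown-1, 2 for knockdown-2, 2 for the mean and 2 between the shRNAs, and fry, which compares a list with no other genes, called 44, 35, 39 and 40. The replicate numbers do not pair the samples, as deviations of same-numbered libraries correlated at 0.043, 0.023 and -0.033. A replicate block gave 7396, 5879, 2280, 5855 and 8148 genes for the same 5 counts. With upper-quartile scaling the larger direction turned in each contrast. Higher and lower genes were 3643 and 3983 with knockdown-1, 3332 and 2742 with knockdown-2, and 3111 and 2982 with the mean. Between the shRNAs they were 4707 and 3708. Of 630 values of named genes, 53 lost the call with DESeq2, 28 with no filter, 6 with upper-quartile scaling, 2 with the block, 1 with limma-voom and 158 in the fit of only the groups compared. Over the 6 fits that each left out a library, 145 of 3780 values lost the call. Depth limits genes with few counts, such as ADCYAP1 with 20 counts over the control libraries.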

Other observations

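The 6 gene lists used here were written after the main results had been seen. Their camera p-values were adjusted over these 6 lists alone and are not comparable with those of the lists fixed earlier. The tests of GC content and length, of the control libraries and of choroid plexus genes were written before their values were seen. Antigen presentation and NF-kB target genes rose with knockdown-1. Of 18 antigen presentation genes, 17 rose with knockdown-1, with a median of 1.52 on the log2 scale (camera adjusted p = 0.0108 with an estimated correlation), and 16 were lower with knockdown-2 than with knockdown-1 (adjusted p = 0.0055 with an estimated correlation). B2M, the light chain of class I molecules, was at 65.5 ± 3.54 CPM in control (SD, n = 2), 261 ± 12.5 CPM with knockdown-1 and 62.4 ± 1.09 CPM with knockdown-2, and TAP1, a peptide transporter gene, at 18.1 ± 1.4, 64.6 ± 0.683 and 13.2 ± 1.34 CPM. Against control, knockdown-2 had 3 antigen presentation genes higher and 7 lower and was not called (camera adjusted p = 0.3191). Of 15 NF-kB target genes, 14 rose with knockdown-1 (adjusted p = 0.0127 with an estimated correlation), including ICAM1, an adhesion molecule gene, from 12.6 ± 0.269 to 33.4 ± 0.0480 CPM and RELB from 2.94 ± 0.260 to 8.06 ± 1.22 CPM. The NF-kB list shares 1 tested gene with the interferon list and the antigen presentation list 0, and CCL5 of the NF-kB list had been named before that list was written. Few shared genes do not show that these lists changed apart from the interferon list, which was not tested. B2M, TAP1, ICAM1 and RELB were chosen after their values were seen.

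Multiciliated cell genes rose with knockdown-2. Of 33, 31 rose, with a median of 1.253 (camera adjusted p = 0.0057 with an estimated correlation), and 32 were higher than with knockdown-1 (adjusted p = 0.0055 with an estimated correlation), 4 of them named before this list was written. With knockdown-1, 20 fell and 1 rose (adjusted p = 0.0639 with an estimated correlation), and 11 fell without knockdown-1 replicate 1. CCNO, which acts in centriole amplification, was at 1.79 ± 0.317, 1.20 ± 0.104 and 11.8 ± 0.205 CPM in control, knockdown-1 and knockdown-2, and RSPH4A, a radial spoke gene, at 5.88 ± 0.378, 1.76 ± 0.780 and 16.8 ± 0.472 CPM. Retinoic acid pathway genes were not called with either shRNA (camera adjusted p = 0.0618 and 0.9907), while CYP26A1, a retinoic acid hydroxylase gene, fell from 3.55 ± 0.0590 to 0.831 ± 0.112 and 0.953 ± 0.371 CPM. CCNO, RSPH4A and CYP26A1 were chosen after their values were seen.

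The higher multiciliated cell genes with knockdown-2 could come from choroid plexus-like cells. The 17 choroid plexus genes had a median difference between the shRNAs of 0.52 on the log2 scale, and of 0.509 to 0.835 over the 15 settings run. These values lie between the bounds set for and against that source, so it cannot be told apart for the multiciliated cell genes. Of the 17 genes, 10 were higher and 1 lower with knockdown-2 than with knockdown-1 (camera adjusted p = 0.1053 with an estimated correlation). Against control, 7 were higher with knockdown-2, 1 was lower and 9 did not pass (camera adjusted p = 0.3076 with an estimated correlation). Among choroid plexus genes, with examples chosen after their values were seen, CLIC6 and LMX1A stood at 440.2 ± 13.6 and 50.1 ± 2.30 CPM in control and 604 ± 9.10 and 91.6 ± 0.280 CPM with knockdown-2, while OTX2 fell from 194 ± 0.0260 to 162 ± 1.34 CPM, TTR stood at 0.606 ± 0.0390 CPM with knockdown-2, and 5 of the 17 are also in a list fixed earlier. A trend with GC content and gene length is argued against, since the median difference of the 33 multiciliated cell genes was 1.68 before and 1.64 after its removal. A change of cell state that differs between the shRNAs stays open as a hypothesis and was not tested.

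Cell cycle genes fell with both shRNAs, with a median of -0.43 over 90 G1/S and G2/M genes in the mean contrast (adjusted p = 0.0265 for G1/S and 0.0628 for G2/M genes with an estimated correlation). After removal of a trend with GC content and length it was -0.42, which argues against that trend as the whole cause. Without either control library it was -0.43 or lower, which argues against 1 deviating control library as the whole cause. The libraries of a group may be technical, so this check cannot show a difference between the control culture and the others. Such a difference cannot be separated from the shRNAs here. The cell cycle fall was not graded with the PRMT7 level, which was 39.9% of control with knockdown-1 and 74.6% with knockdown-2. The G1/S medians were -0.41 and -0.54, and the G2/M medians -0.36 and -0.44, in that order. Slower division after a lower PRMT7 level may account for the pattern, as may a response to hairpin expression as such, and neither was tested.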
